A study of Drosophila melanogaster with 10 samples.

How the data were processed

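Gene expression was measured in neurons sorted from cultures of Drosophila melanogaster embryo cells. Per the labels, cells were dissociated from embryos at the start of gastrulation, cultured for 5 to 7 days and sorted by fluorescence. Total RNA of the positive cells was labelled with biotin and hybridised to an Affymetrix expression array. The study compared 2 reporter strains with 5 samples each. In the strain called Cha here, 7.4 kb of regulatory DNA of the choline acetyltransferase gene drove Gal4, which switched on green fluorescent protein. In the strain called Gad here, 2.1 kb of regulatory DNA of the glutamate decarboxylase gene drove a red fluorescent protein. Groups and replicate numbers were taken from the sample titles. No array of unsorted or of reporter-negative cells was used here, and detection calls and scanner files were not used here.

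The deposited values were log2 expression values made by the authors with RMA, per the submitters' processing notes, whose version was not given in the sources used here. RMA subtracts background, brings all arrays to 1 distribution and summarises the probes of each probe set, so a shift of most genes in 1 direction is removed. The array medians of the deposited values lay between 5.7 and 5.78, and the values ran from 2.95 to 15.06. RMA has no true zero, so differences of dim genes are compressed. The number of arrays limits the precision, and the labels do not say that the samples came from separate cultures. All p-values therefore measure only the spread between these samples, which may be technical.

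The table held 18952 probe sets, of which 183 were control probe sets and 18769 were tested. In the platform annotation used here, 13647 of these had 1 gene symbol, 402 had several and 4720 were unnamed. No gene was named from a probe set with several. Entrez identifiers were looked up in the gene table of the Release 6 assembly, which changed 0 symbols, and 103 probe sets had an identifier absent from it. For the comparison of genes, the probe set with the highest mean over the 10 arrays stood for each of 11983 genes. Of these, 1094 had more than 1 probe set of their own, and other probe sets of a gene named in the report that did not pass, or passed in the other direction, are given beside it or as a range. A gene called w could not be measured this way.

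Differences are log2 values of Cha minus Gad. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) without covariates. P-values were adjusted by the Benjamini-Hochberg method over all probe sets or over all genes, with a threshold of 0.05. Gene lists of at least 3 measured genes were tested with camera and a preset correlation between genes of 0.01, adjusted over the 32 lists. Each list was also tested with a correlation estimated from its own genes and with fry. Single values outside this fit were compared with exact permutation tests, whose smallest 2-sided p with 5 against 5 arrays is 0.00794.

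Before the data were examined, the tests, the 32 lists, the alternatives and a rule for naming genes were fixed. The rule took ChAT, VAChT, Gad1 and VGAT. It added the 10 genes highest in Cha and the 10 highest in Gad among those past the threshold whose groups did not overlap. It also took up to 4 members of each list, those past the threshold first and with the smallest p, or up to 2 where none passed. Alternatives covered a second quantile normalization, cyclic loess, median centring and removal of dim probe sets. A probe set was dim unless it lay above the percentile 40 of its array on at least 5 arrays. Other alternatives were a trended and robust prior, array weights, the replicate number as a block, and leaving out the 2 arrays that share a letter code. Further ones were leaving out each array, averaging the probe sets of a gene, stricter thresholds and an exact rank-sum test. The average of the closest pair of Gad arrays, and lists without Cyp1, Cyp40 and qm, were added after the data were seen.

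The limma step was tested on simulated data with the 18769 probe sets of the Cha versus Gad comparison and 200 seeded changes. It recovered 52.2% of the changes of 0.5 on the log2 scale, 83.6% of those of 1 and 97% of those of 2. Unchanged probe sets made up 4.9% of the calls. The real comparison called 2657 probe sets, far more than the 200 seeded, and the adjustment depends on that share. The recovery rates therefore need not hold for the real comparison. The camera step called the 1 shifted list of 40 simulated ones and 0 of the others. The simulated genes varied independently of each other, whereas the correlation estimated from the real muscle list was 0.54. The simulation therefore cannot show how often camera calls lists of correlated genes wrongly.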

Results

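The data set compared neurons sorted from embryo-cell cultures of 2 Drosophila reporter strains, with 5 arrays labelled Cha and 5 labelled Gad. The question was how cells marked through cholinergic regulatory DNA differ in gene expression from cells marked through GABAergic regulatory DNA. Arrays of 1 group correlated with each other at r = 0.971 to 0.990 for Cha and 0.989 to 0.997 for Gad over all tested probe sets, and arrays of different groups at 0.954 to 0.983. The first principal component held 50.9% of the variance and separated the groups. The median SD of a probe set over the 5 arrays was 0.211 in Cha and 0.149 in Gad. The arrays of Gad replicates 4 and 5 were the closest pair, with an SD of their difference of 0.188 against 0.28 for the next closest Gad pair.

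The genes behind the reporters were compared first. ChAT, which encodes the enzyme that makes acetylcholine, had a log2 value of 11.39 ± 0.44 (SD, n = 5) in the arrays labelled Cha and 10.71 ± 0.39 in those labelled Gad. The difference of 0.68 (95% interval 0.17 to 1.20) did not pass the threshold (limma adjusted p = 0.067). VAChT, the vesicular acetylcholine transporter nested in the same locus, differed by 0.22 (adjusted p = 0.43). Gad1, the enzyme that makes GABA, stood at 12.49 ± 0.30 in Cha and 12.37 ± 0.19 in Gad, a difference of 0.12 (interval -0.21 to 0.45, adjusted p = 0.626). VGAT, the vesicular GABA transporter, differed by 0.49 (interval -0.03 to 1.01, adjusted p = 0.186), with the higher mean in Cha. Exact permutation tests of the 4 genes gave p = 0.0556, 0.294, 0.46 and 0.103. Gad1 and VGAT were thus not higher in the arrays labelled Gad, so directions below refer to the labels of the arrays and not to a measured enrichment of either transmitter. Without Cha replicate 4, VGAT was past the threshold with the higher level in Cha (0.70, adjusted p = 0.0148), and without Cha replicate 4, Cha replicate 5 or Gad replicate 4, ChAT was past it (0.81, 0.80 and 0.79).

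**Figure D1:**
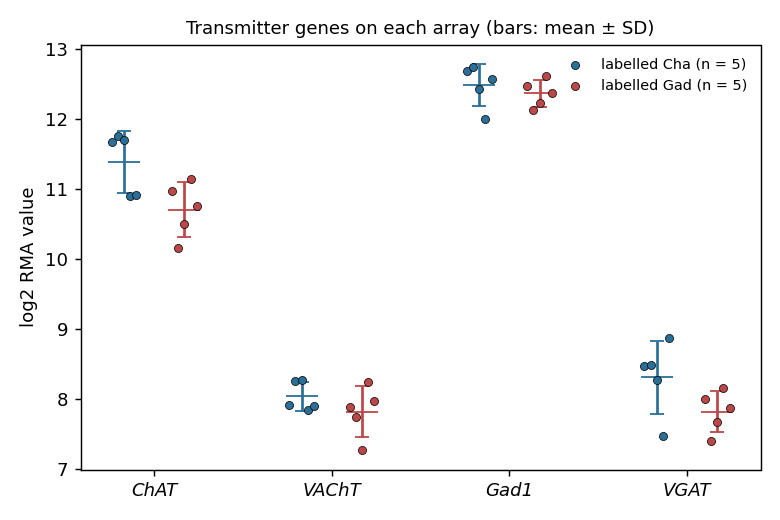
Log2 RMA values of 4 transmitter genes on each array; points are arrays (5 labelled Cha, 5 labelled Gad) and bars the mean ± SD. The 2 groups overlap for all 4 genes, with Gad1 means of 12.49 and 12.37.

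Among genes whose groups did not overlap, the largest differences were not in transmitter genes. Cyp6a17, a cytochrome P450, was higher in Gad (4.01 ± 0.26 against 10.86 ± 0.25, SD, n = 5, adjusted p = 1.09e-09). It was dim on all 5 Cha arrays, as CG4757 was there and lncRNA:CR42646 on all 5 Gad arrays, so the folds of these 3 genes are uncertain. Of the genes named next, CG33462 was dim on 4 arrays of its lower group, CG14687 on 3, KaiR1D and alphaTub84D on 2, and CG13056 and Idgf5 on 1, so their folds are uncertain too. Further below, cid, dsx, baz, shg and Lsp2 had Cha means of 4.52, 4.07, 4.74, 4.69 and 4.47. These lie under the percentile 40 of every Cha array (4.77 to 4.84). The Gad mean of mthl8 (4.7) likewise lies under that of every Gad array (4.75 to 4.82), so these folds are also uncertain. Other genes far higher in Gad were Obp99a, an odorant-binding protein (difference -3.82, SE 0.33), the neprilysin-like genes Nepl21 (-3.70) and Nepl11 (-3.63), and Sid, a nuclease gene (-3.68). CG4757 (-3.93), CG33462 (-3.80), CG17999 (-3.80), CG13056 (-3.77) and Idgf5, an imaginal disc growth factor (-3.64), completed the 10 highest in Gad of this kind; Lsp2 (-4.64) had overlapping groups. In Cha, lncRNA:CR42646 (4.95, SE 0.33) and Hrb87F, an RNA-binding protein of the hnRNP class (4.16, SE 0.16), led, followed by CG10353 (3.54), PPO1, a prophenoloxidase (3.39), and CG14687 (3.37). KaiR1D, a kainate-type glutamate receptor subunit, was higher in Cha (3.36), and Idh3g (3.24), fred (3.15), alphaTub84D (2.90) and Hmt-1 (2.89) followed. In total 2212 of 11983 genes passed the threshold, 984 higher in Cha and 1228 higher in Gad, and 188 and 516 of these differed at least 2-fold. The 2 groups did not overlap in 1622 genes, or 13.5%, where chance gives 0.79%. Of the 18769 probe sets, 2657 passed, 1254 higher in Cha and 1403 in Gad. Without Gad replicate 3, 1377 genes passed, 1369 of them among the 2212.

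**Figure D2:**
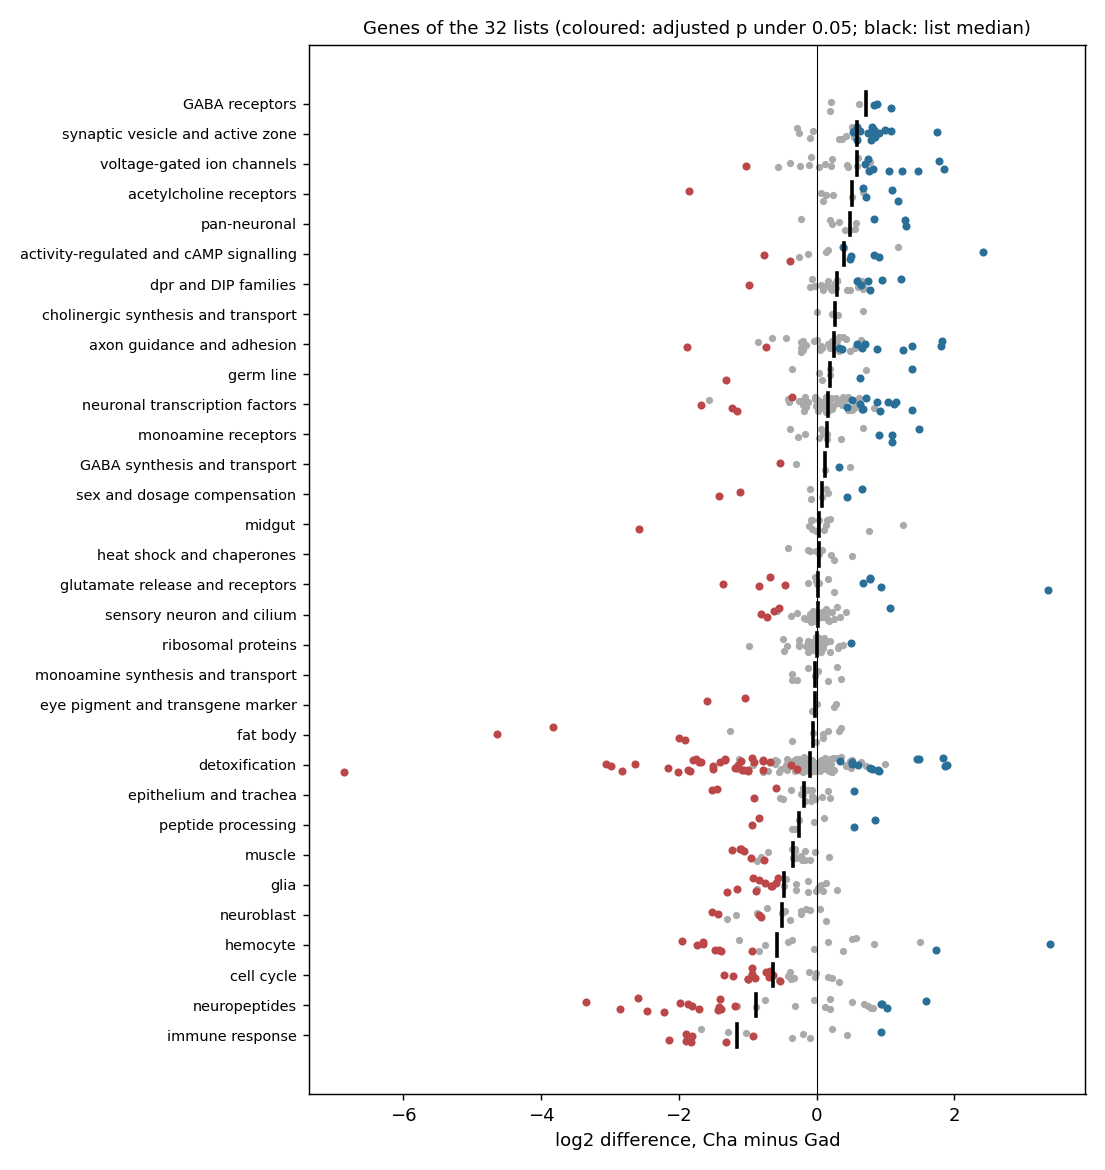
Log2 difference (Cha minus Gad) of each measured gene in the 32 lists; coloured points passed an adjusted p of 0.05 (blue higher in Cha, red higher in Gad), grey points did not, and black bars are list medians. The synaptic list has a median of 0.59, the neuropeptide list of -0.88 and the cell cycle list of -0.63.

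Synaptic and pan-neuronal genes that passed the threshold were higher in Cha, as were those of voltage-gated channels with 1 exception. Of 26 genes of synaptic vesicles and the active zone, 15 were higher in Cha and 0 in Gad (18 and 0 adjusted over the list alone), with a median difference of 0.59. Syn, which encodes synapsin, was 3.36-fold higher (11.51 ± 0.21 against 9.77 ± 0.42), Sap47 1.99-fold, EndoA 1.75-fold and Csp 1.51-fold. Among 25 voltage-gated channel genes, 9 were higher in Cha and 1 in Gad (13 and 1 adjusted over the list alone). The potassium channel genes Sh (1.78, SE 0.27) and slo (1.85, SE 0.31), the sodium channel gene para (1.47, SE 0.23) and Slob, whose product binds the slo channel (1.24), were among the 9. Of 11 pan-neuronal genes, 3 were higher in Cha (4 adjusted over the list alone): futsch (1.30), the RNA-binding protein gene fne (1.29) and nrv3 (0.83). Other probe sets of futsch gave 0.09 and -0.04, of Slob 0.08, of Sh -0.21 to 1.30, and of Sap47 0.70 (adjusted p = 0.0798). The futsch probe set at 0.09 (means 4.7 and 4.6) and the Sh probe set at -0.21 (3.94 and 4.15) were too dim to weigh against the calls. The camera test called these lists with adjusted p = 8.99e-06, 0.00531 and 0.0236. With an estimated correlation, the adjusted p was 0.596, 0.619 and 0.619. The glia list lay in the other direction (median -0.47), as did the cell cycle list (-0.63). The pan-neuronal call ended without Cha replicate 2 (0.067) or Gad replicate 2 (0.0525). The count of 15 synaptic genes was 9 without Cha replicate 2, Gad replicate 2 or Gad replicate 3.

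Receptor genes followed in part. Of 11 acetylcholine receptor genes, 4 were higher in Cha and 1 in Gad (5 and 1 adjusted over the list alone). nAChRbeta2 (1.18), nAChRalpha5 (0.68) and the muscarinic receptor gene mAChR-B (1.09) were higher in Cha, and nAChRbeta3 (-1.85, SE 0.46) in Gad. Of 6 GABA receptor genes, 3 were higher in Cha (3 adjusted over the list alone): CG8916 (1.08), Lcch3 (0.88) and GABA-B-R3 (0.83). The camera adjusted p was 0.0328 and 0.0117, and 0.619 and 0.596 with an estimated correlation. The acetylcholine receptor call ended without Cha replicate 1 (0.0641), 2 (0.067) or 3 (0.0507) or Gad replicate 2 (0.0695). Of 14 monoamine receptor genes, 4 were higher in Cha and 0 in Gad (4 and 0 adjusted over the list alone), among them DopEcR (1.48) and the dopamine receptor genes Dop1R1 (1.10) and Dop2R (0.90), with Octbeta1R (1.10; 0.03 and 0.20 on 2 other probe sets) for octopamine; the list did not pass (camera adjusted p = 0.116). Glutamate genes split, with 5 of 16 higher in Cha and 4 in Gad (5 and 4 adjusted over the list alone): KaiR1D (3.36) and Ekar (0.78) against GluRIIB (-1.36) and GluRIID (-0.84), camera adjusted p = 0.73. Dop2R lost its call in 8 of the 10 fits that left out 1 array, Lcch3 and Octbeta1R in 6, and GABA-B-R3 in 2.

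Cell surface and signalling genes included some of the larger neuronal differences. Of 30 genes of the dpr and DIP families of interacting surface proteins, 6 were higher in Cha and 1 in Gad (9 and 1 adjusted over the list alone). Examples were dpr7 (1.22), dpr10 (0.78) and dpr17 (0.75), and DIP-epsilon (-0.98) in the other direction, although 2 other probe sets of DIP-epsilon differed by -0.08 and -0.01. Of 40 axon guidance and adhesion genes, 10 were higher in Cha and 2 in Gad (11 and 4 adjusted over the list alone), led by Ten-a (1.82, SE 0.19), Drl-2 (1.80, SE 0.18) and kirre (1.38). Other probe sets of Ten-a gave 0.04 and 0.14, and that of kirre 0.02. Those of Ten-a at 0.04 (means 4.02 and 3.98), of kirre (4.35 and 4.34) and of DIP-epsilon at -0.08 (3.96 and 4.04) were too dim to weigh against the calls. Ptp99A was higher in Cha by 1.25 on its brightest probe set and by 2.05 on a second one, while 4 others did not pass (-0.45, -0.07, -0.03 and 0.21). Of 14 activity-regulated and cAMP signalling genes, 6 were higher in Cha and 2 in Gad (8 and 2 adjusted over the list alone). The transcription factor gene sr (2.41, SE 0.29), Nf1 (0.91) and the phosphatase gene puc (0.39) were higher in Cha, and the kinase gene for (-0.76) in Gad. The camera adjusted p was 0.00359 for the dpr and DIP list, 0.116 for axon guidance and 0.0343 for the activity list. With an estimated correlation, it was 0.619, 0.672 and 0.619. The activity call ended with averaged probe sets (0.112), without Cha replicate 1, 2 or 5 or Gad replicate 2 (0.051 to 0.0746), and without the 2 arrays that share a letter code (0.0534). The count of dpr and DIP genes higher in Cha was 13 without Cha replicate 4 and 3 without Cha replicate 2 or Gad replicate 1, 3 or 5. That of axon guidance genes was 4 to 6 without Cha replicate 2 or 3 or Gad replicate 1, 2, 3 or 5.

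Neuropeptide genes that passed the threshold were more often higher in Gad. Of 31 measured, 14 were higher in Gad and 4 in Cha (15 and 6 adjusted over the list alone), with a median difference of -0.88. Eh, the eclosion hormone gene, was 7.23-fold higher in Gad (6.19 ± 0.59 against 9.05 ± 0.60), the insulin-like peptide gene Ilp2 6.02-fold, the myosuppressin gene Ms 5.51-fold and Nplp1 3.67-fold. Among 9 peptide processing genes, the proteases Fur2 (-0.84) and svr (-0.94) were higher in Gad, and the dense-core vesicle genes Cadps (0.85) and IA-2 (0.55) in Cha (2 and 2 adjusted over the list alone). The camera adjusted p was 0.00169 for neuropeptides and 0.348 for processing. With an estimated correlation it was 0.596 and 0.672. IA-2 gave 0.09 and 0.19 on 2 other probe sets and lost its call in 7 of the 10 fits that left out 1 array.

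**Figure D3:**
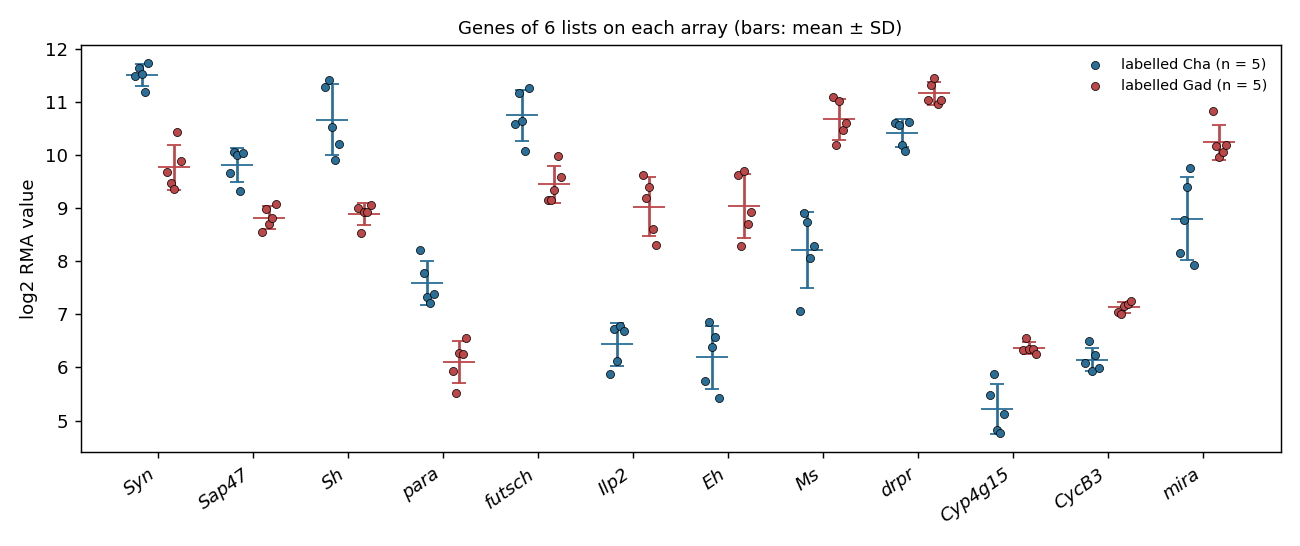
Log2 RMA values of 12 genes from synaptic, channel, pan-neuronal, neuropeptide, glial, and dividing-cell lists on each array; points are arrays (5 labelled Cha, 5 labelled Gad) and bars the mean ± SD. For each gene shown the groups do not overlap, with Syn at means of 11.51 and 9.77 and Eh at 6.19 and 9.05. The 12 are a selection of named genes, and others of the same lists, such as EndoA, nrv3 and grh, had overlapping groups.

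Genes of glia, muscle, neuroblasts and dividing cells that passed the threshold were higher in Gad. Of 23 glial genes, 10 were higher in Gad and 0 in Cha (13 and 1 adjusted over the list alone), among them Cyp4g15 (-1.15), zyd (-0.83), the engulfment receptor gene drpr (-0.75) and CG6126 (-0.66). Of 25 cell cycle genes, 13 were higher in Gad (14 adjusted over the list alone), among them the cyclin gene CycB3 (-0.99), the kinesin gene ncd (-0.94), the centromere gene cid (-0.93) and dup (-0.89). Of 17 neuroblast genes, 4 were higher in Gad (5 adjusted over the list alone): grh (-1.52), mira (-1.43), pon (-0.84) and baz (-0.81). Of 21 muscle genes, 6 were higher in Gad (9 adjusted over the list alone), among them Prm for paramyosin (-1.22), the myosin light chain gene Mlc2 (-1.10), Act87E (-0.95) and Zasp66 (-0.77). Other probe sets of Zasp66 gave -0.42 (adjusted p = 0.0635) and -0.06, and that of grh 0.11; Act87E lost its call in 6 of the 10 fits that left out 1 array. The brightest members of the lists, named after their values were seen, were moody for glia (11.57 in Cha, 12.03 in Gad, adjusted p = 0.0601), wor for neuroblasts (9.29 and 10.47, adjusted p = 0.0589) and Argk1 for muscle (12.41 and 12.23, adjusted p = 0.43). The camera adjusted p was 5.54e-05, 1.68e-06, 0.000436 and 0.000397. With an estimated correlation it was 0.596, 0.596, 0.596 and 0.619. The count of 6 muscle genes was 10 without Cha replicate 4 and 3 without Cha replicate 1, 3 or 5 or Gad replicate 3, 4 or 5. Of the RNA quality controls, the gap between 3′ and 5′ probe sets was 2.91 ± 0.38 in Cha and 3.41 ± 0.19 in Gad for GAPDH (exact p = 0.0317, adjusted over 3 controls 0.0952). For actin it was 5.47 and 5.48, and for eIF4a 5.25 and 4.98 (exact p = 0.984 and 0.214).

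Blood cell, immune and detoxification genes passed the threshold in both directions, and fat body genes only toward Gad. Of 22 hemocyte genes, 8 were higher in Gad and 2 in Cha (12 and 5 adjusted over the list alone). The factor gene srp (-1.73) and the laminin gene LanA (-0.93) were higher in Gad, and the prophenoloxidase genes PPO1 (3.39, SE 0.34) and PPO2 (1.73, SE 0.25), known from crystal cells, in Cha. Of 13 fat body genes, 4 were higher in Gad (5 adjusted over the list alone): Obp99a (-3.82), Pepck1 (-2.0), Lsd-1 (-1.91) and Lsp2 (-4.64), the last with overlapping groups and an SD of 3.20 in Gad. The list median was -0.05 and the mean -1.0. Lsp2 lost its call in 3 of the 10 fits that left out 1 array. Of 16 immune genes, 7 were higher in Gad and 1 in Cha (9 and 1 adjusted over the list alone), among them AttD (-1.90), PGRP-SC2 (-1.82) and PGRP-LB (-1.31), while dl was higher in Cha (0.93; 0.54 on another probe set, adjusted p = 0.0831). Of 142 genes in the detoxification list, 34 were higher in Gad and 13 in Cha (38 and 16 adjusted over the list alone), such as Cyp6a20 (-1.71), Cyp9c1 (-1.09) and Cyp4p1 (1.86). The list was drawn by symbol and also held the cyclophilin genes Cyp1 and Cyp40, without which 34 and 12 of 140 passed (camera adjusted p = 0.00727). The camera adjusted p was 0.0328, 0.0328, 0.00127 and 0.0117 for these 4 lists. With an estimated correlation it was 0.62, 0.596, 0.596 and 0.619. The hemocyte call ended with loess (0.0781), removal of dim probe sets (0.0733) and array weights (0.055), and the fat body call with removal of dim probe sets (0.0896). The hemocyte call also ended without Cha replicate 2 or 4 or Gad replicate 2 (0.051 to 0.204) or the 2 arrays that share a letter code (0.0539), the fat body call without Cha replicate 2 or 5 (0.0504 and 0.0801) and the detoxification call without Cha replicate 2 (0.0746). Without Gad replicate 3, the detoxification count in Gad was 22.

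The other lists did not pass the camera test on the deposited values. Among 71 neuronal transcription factor genes, 12 were higher in Cha and 4 in Gad (15 and 6 adjusted over the list alone; adjusted p = 0.0592), with vg (1.15; 0.33 on another probe set), Antp (1.03; 0.68 and 0.04) and tll (-1.68). This list passed with a second quantile normalization (0.0357), loess (0.0369) and removal of dim probe sets (0.0351). With an estimated correlation its adjusted p was 0.672. The gene jim was higher in Cha by 0.88 on its brightest probe set and lower by -0.60 on another, with -0.22 on 1 more. Of 20 epithelial and tracheal genes, 4 were higher in Gad and 1 in Cha (4 and 1 adjusted over the list alone; adjusted p = 0.0589), among them Ect3 (-1.45), Cht2 (-0.91) and shg (-0.59), whose call ended in 7 of the 10 fits that left out 1 array. The epithelial list passed with median centring (0.0465), the trended prior (0.0488) and array weights (0.0219). With an estimated correlation its adjusted p was 0.658. Of 35 sensory neuron and cilium genes, 4 were higher in Gad and 1 in Cha (4 and 1 adjusted over the list alone; adjusted p = 0.711), including the channel genes pyx (-0.72) and pain (-0.54), Oseg4 (-0.62) and betaTub85D (1.07). Of 9 germ line genes, bam (1.38) and aub (0.63) were higher in Cha and piwi in Gad (-1.32) (2 and 1 adjusted over the list alone; adjusted p = 0.509). Of 9 genes of sex determination and dosage compensation, fru (-1.11) and dsx (-1.41) were higher in Gad, and Sxl (0.66) and tra (0.44) in Cha (2 and 2 adjusted over the list alone; adjusted p = 0.964). The list's median of 0.08 and mean of -0.13 differed in sign. Other probe sets of fru ranged from -0.58 to 0.10, and those of Sxl gave 0.67 (adjusted p = 0.0686) and 0.78. Sxl and tra lost their calls in 8 of the 10 fits that left out 1 array, aub in 5, pain in 3 and Ect3 in 2.

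Several lists held few or no differences. Of 13 midgut genes, LManII was higher in Gad (-2.58; 1 adjusted over the list alone; adjusted p = 0.908). Of 6 eye pigment and transgene marker genes, bw (-1.59) and ry (-1.04) were higher in Gad (2 adjusted over the list alone; adjusted p = 0.348), with a second bw probe set at 0.01 and the bw call lost in 4 of the 10 fits that left out 1 array. Of 5 genes of GABA synthesis and transport, Ssadh (0.32, call lost in 9 of these 10 fits) was higher in Cha and Gabat (-0.53) in Gad (1 and 2 adjusted over the list alone; adjusted p = 0.908). Of 42 genes in the ribosomal protein list, of which qm encodes no ribosomal protein, RpL27 was higher in Cha (0.50; 1 adjusted over the list alone; adjusted p = 0.711). The 4 cholinergic genes included 0 past the threshold (0 adjusted over the list alone; adjusted p = 0.348), with Ace, acetylcholinesterase, at 0.31 (SE 0.22). The 9 genes of monoamine synthesis and transport also included 0 (0 adjusted over the list alone; adjusted p = 0.695), with Tdc2 at -0.35 (SE 0.14) and DAT at -0.35 (SE 0.23). The 9 heat shock genes included 0 (0 adjusted over the list alone; adjusted p = 0.964), with Hsp26 at 0.52 (SE 0.22) and Hsc70-3 at -0.42 (SE 0.18). Over the 32 lists, camera called 16 with the preset correlation, 7 higher in Cha and 9 in Gad, and 0 with estimated correlations, where 1 list, glia, had an unadjusted p of 0.0218; fry, which tests each list on its own, called 9. In 14 of 100 splits of the arrays into 5 and 5, the real one included, at least 16 lists were called, so the number of lists called did not exceed what other groupings of these arrays gave.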

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

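Tests chosen after the result was seen were those of the share of non-neuronal cells, of RNA quality and of exchanged labels; the others were written first. In 324 groups of 5 arrays, 20 had an array far from the other 4, or 6.2%, where chance gives about 1 in 20. Of these 20 arrays, 8 were Cha replicate 4 and 7 were Gad replicate 2.

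On Cha replicate 4, nrv3 was low at 12.20 against 12.73 to 12.87 on the other Cha arrays (gap 0.784 of the range), and Nepl11 at 5.91 against 9.22 to 10.12 (0.788), while PPO2 was high at 10.50 against 9.15 to 9.51 (0.733). The mean of the acetylcholine receptor list on that array, each gene taken relative to its mean over the 10 arrays, was -0.37 against 0.25 to 0.35 (0.864). That of the GABA receptor list was -0.21 against 0.34 to 0.53 (0.743), and that of the dpr and DIP list -0.25 against 0.21 to 0.38 (0.725). Some lists not past this rule lay within the range of the Gad arrays on Cha replicate 4. The synaptic list was at -0.079 (Gad -0.606 to 0.019) and the pan-neuronal list at -0.191 (Gad -0.788 to 0.179). The neuroblast list was at 0.22 (Gad 0.177 to 0.615) and the muscle list at 0.297 (Gad -0.007 to 0.53). On Cha replicate 1, CG33462 was high at 6.88 (0.76) and Ssadh low at 10.43 (0.912), and on Cha replicate 2, Cyp6a17 was at 4.46 against 3.81 to 3.99 (0.721). On Gad replicate 2, Dop1R1 (5.65, gap 0.826), Octbeta1R (8.41, 0.789), Sh (8.54, 0.729), grh (9.43, 0.727) and RpL27 (12.10, 0.787) were low. On the same array pyx (6.39, 0.837) and the midgut list (0.15, 0.734) were high. On Gad replicate 1, mira was high (10.82, 0.752), and on Gad replicate 3, jim was low (11.98, 0.791).

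Control probe sets were outside the main measurement. Of 100 that carry the fly label of the array's control series, 3 differed by at least 1 on the log2 scale, and the others by at most 0.35. AFFX-Dm-M62653-1_s_at was higher in Cha by 9.67 and AFFX-Dm-AF292560-1_s_at by 9.35. AFFX-Dm-K01486-1_at was higher in Cha by 1.97. The first 2 were lowest among the Cha arrays on replicate 4, at 11.88 (gap 0.854 of the range) and 11.91 (0.866), against 13.41 or more on the other Cha arrays. Which transcripts these 3 probe sets detect was not given in the tables used here, and whether they detect sequences of the Cha strain's own reporter constructs, which would make these differences a property of the strain, was not settled. Of the 83 other control probe sets, 16 differed by at least 1, all of them higher in Cha and lowest on Gad replicate 1. AFFX-r2-Bs-dap-3_at was higher by 2.33 (exact p = 0.0397), at 3.48 on Gad replicate 1 against 9.72 to 10.65 on the other Gad arrays, AFFX-r2-Bs-thr-3_s_at by 1.87 and AFFX-r2-Bs-phe-3_at by 1.74. Without that array, 10 of these 16 still differed by at least 1, and 15 of the 83 did, the most by 1.32. AFFX-r2-Ec-bioB-3_at was higher in Cha by 0.96 (exact p = 0.0238), with Gad replicate 1 the highest of the Gad arrays there. The other control probe sets whose names hold bio or cre were also higher in Cha, by 0.38 to 0.91.

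The first pattern weighed was that synaptic and other neuronal lists were higher in Cha, while glia, muscle, neuroblast and cell cycle lists were higher in Gad. The first explanation was a larger share of non-neuronal cells in the arrays labelled Gad, which a sort on the reporter would be meant to remove. The test assumed that the markers of all other cell types would then rise alike, which need not hold if their shares differ. The 8 lists of such markers were not shown to lie further apart than permuted genes (permutation p = 0.204, 123 genes), so the explanation stays open. Of the 137 measured markers in the 8 lists, 4 are also in another list. The means of these lists ran from -0.82 for fat body (SD over genes 1.39) and -0.64 for neuroblasts (0.46) to -0.07 for midgut (1.05) and 0.18 for germ line (0.80), PPO1 (3.39) and PPO2 (1.73) of the hemocyte list were higher in Cha, and neuropeptide genes, with a mean of -0.72, are not part of this pattern. A difference in RNA quality was predicted to move the gap the same way in all 3 controls. The differences were -0.01 for actin, 0.27 for eIF4a and -0.51 for GAPDH, so a shared shift was not shown. Since GAPDH differed (unadjusted exact p = 0.0317), RNA quality stays open. How the 16 of 83 other control probe sets that were higher in Cha by at least 1 bear on this pattern was not tested. A difference between the marked neurons themselves stays open and untested, because reporter, strain and group coincide. Control probe sets outside the main measurement also differed with group, so a difference in how the samples were handled cannot be told apart from group either.

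The second pattern was that Gad1 and VGAT were not higher in the arrays labelled Gad. Labels exchanged between some of the arrays would put arrays of both groups on the other group's side of the first principal component of all tested probe sets, which was found without the labels, and 0 of 10 arrays lay there. A signal too high for differences to show would leave few calls among bright genes, but 17.8% of the 146 genes at least as bright as Gad1 passed the threshold, and VGAT, at a mean of 8.07, was dimmer than Gad1 at 12.43. The 3 control probe sets above, higher in Cha, would exclude an exchange of all labels if they detect the constructs of the Cha strain, which the tables used here do not say. Gad1 was bright in both groups, at 12.49 in Cha and 12.37 in Gad, with a mean above that of 98.6% of genes. Why samples of both kinds held it stays open and untested, since no unsorted cells were used here.

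The last pattern was the set of 20 largest differences among genes whose groups did not overlap. Alleles without expression in 1 strain would leave the lower group dim on all 5 arrays, if nothing else gave signal on the probe set. This held for 3 of the 20 genes, Cyp6a17, CG4757 and lncRNA:CR42646. In 11 of the 20, no array of the lower group was dim, which argues against alleles without signal as the source of the whole set. Strain variants that lower a signal without leaving it dim were not tested. A strain variant may be the source for any of the 20 genes, since strain and group coincide in this design.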

How the results depend on the processing

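No gene named by the rule changed direction under any alternative in which it was measured, and the 3 other scalings moved the median difference of all genes from 0.044 to between 0.006 and 0.061. The 1254 probe sets higher in Cha and 1403 in Gad became 1432 and 1336 with median centring, 1028 and 1538 with loess, and 1543 and 1531 with array weights. Of the 118 named genes past the threshold, 0 to 4 lost it under other scalings, priors, weights, the dim filter and probe set averages, 28 with the block, 34 without the letter-code pair, 6 with the closest-pair average, and 1 to 16 without single arrays. The sample numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.37 to 0.03, and 0 of 5 Cha arrays correlated best with the Gad array of its number. With this replicate block, 1366 probe sets (474 and 892) and 1113 genes passed (1338 and 1096 among the main ones), and of the lists only acetylcholine receptors lost its call. Leaving out both arrays with the same letter code gave 1235 and 1055, adjusted p under 0.01 gave 1031 and 870, and a limit of 2-fold gave 821 and 704. The exact rank-sum test called 0 and 0 after adjustment (smallest adjusted p 0.0698 and 0.0586) and 4008 and 2974 at an unadjusted p under 0.05. With 5 against 5 arrays its p cannot go below 0.00794. The 2133 probe sets and 1622 genes at that p were too few to pass after adjustment. Leaving out single arrays gave 1639 to 3206 probe sets and 1377 to 2614 genes, both lowest without Gad replicate 3 and highest without Cha replicate 4. Averaging the closest pair of Gad arrays, chosen after seeing the data, gave 2159 and 1836. ChAT passed with array weights (0.74) and ran from 0.55 to 0.81 over left-out arrays; VGAT ran from 0.35 to 0.70. VAChT and Gad1 stayed below the threshold in all alternatives run. The number of lists called was 16 without Cyp1, Cyp40 and qm (chosen after seeing the data), 0 with estimated correlations, 9 with fry, and 10 to 19 over left-out arrays, lowest without Cha replicate 2, which ended the calls of acetylcholine receptors, pan-neuronal, hemocyte, fat body, detoxification and activity genes. Without Gad replicate 2, 13 lists were called, and acetylcholine receptors, pan-neuronal, hemocyte and activity genes lost their calls. Activity genes also lost theirs without Cha replicate 1 or 5 or the letter-code pair, acetylcholine receptors without Cha replicate 1 or 3, hemocytes without Cha replicate 4 or that pair, and fat body without Cha replicate 5. Some lists that did not pass turned direction in the camera test and stayed below the threshold. Their mean differences relative to all genes were, for sex determination, -0.095 (quantile), -0.117 (loess), -0.055 (array weights), 0.017 (probe set mean) and -0.123 (fry), and -0.172 to -0.062 over left-out arrays. They were 0.03 (loess) and -0.046 to 0.111 for heat shock, and 0.133 (dim probe sets removed) and -0.024 to 0.105 for GABA synthesis. Over left-out arrays they were -0.074 to 0.065 for midgut, -0.132 to 0.093 for monoamine synthesis, -0.07 to 0.02 for ribosomal proteins and 0.168 to 0.282 for glutamate. Lower counts with left-out arrays and the block follow in part from fewer samples or degrees of freedom, and those with stricter thresholds from their construction; for the other changes the cause was not tested. In 100 of the 126 possible splits of the arrays, the real one included, no other split called as many probe sets (2657, highest other 0, with 5226 and at most 3325 at an unadjusted p under 0.05 by limma) or genes (2212, highest other 158). The count of 1 in each case is the smallest that 100 splits with the real one can give. Calls of probe sets and genes thus exceeded those of the other groupings drawn. This does not exclude a chance difference if the samples were not from separate cultures. For lists the real grouping did not stand out: 14 of the 100 splits called 16 or more, with 19 as the highest. Precision is limited by the number of arrays, and signal over background was not used here.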

Other observations

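Gene families defined by their symbols were examined after the data were seen, with 79 families of at least 8 measured genes. The neprilysin-like family, which encodes relatives of peptide-cleaving metalloproteases, stood out: of 19 measured members, 15 were higher in Gad and 1 in Cha, with a median difference of -2.09. Nepl21 (-3.70), Nepl19 (-3.60), Nepl13 (-3.26) and Nepl6 (-3.21) were the largest besides Nepl11, and Nepl3 was the exception at 0.58. The serpin family, named Spn, had 9 of 27 members higher in Gad and 1 in Cha, led by Spn88Eb (-2.73) and Spn43Ad (-1.67). Of 11 Alg genes, which act in the building of N-linked glycans, 5 were higher in Gad and 0 in Cha, with Alg3 at -1.03. The camera adjusted p over the 79 families was 3.58e-07 for Nepl, 0.0134 for Spn and 0.0103 for Alg. With an estimated correlation it was 0.902 for each.

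In the other direction, 5 of 32 tetraspanin genes (Tsp) were higher in Cha and 0 in Gad, led by Tsp42Er (1.55), with a camera adjusted p of 0.0467 and 0.902 with an estimated correlation. Of 20 genes with a Rab symbol, 7 were higher in Cha and 2 in Gad, among them Rab3, a small GTPase of synaptic vesicles (0.63), and Rab3-GEF (1.12), while Rab3GAP1 was higher in Gad (-0.58). That family did not pass (camera adjusted p = 0.182). The methuselah-like receptor genes mthl8 (2.28) and mthl14 (2.07) were higher in Cha, with 3 of 14 members past the threshold and a family adjusted p of 0.083.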
